A study of Homo sapiens with 58 samples.

How the data were processed

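The series holds bulk total-RNA sequencing of liver tissue from patients with hepatocellular carcinoma, the main primary cancer of hepatocytes. Each of the 58 libraries comes from a piece of tumor (11 libraries), of tumor margin (22) or of non-tumor liver (25), as given in the labels. Donors are represented by arbitrary numbers. The titles name 26 donors, of whom 11 had all 3 tissues and 19 had exactly 1 Margin and 1 Non-tumor library. Of these 19, 8 had no tumor library. A donor code sits on 2 Non-tumor libraries, so the 3 libraries with that code were left out of paired tests and kept in the gene fit. For 1 of the 2 Non-tumor libraries with that code, the column name and the title differ in the donor code. The title was used, and the column name was tried as an alternative in the gene fit, not in the list tests. Under its column name this library would share a donor with a Margin library that has no Non-tumor partner here.

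Per the labels' protocols, libraries were made with a stranded total-RNA kit, and 4 samples with little RNA were made with a low-input kit and run on another sequencer. The labels do not mark which 4, so this batch could not be entered in a fit. Per the submitters' processing notes, the steps named are cutadapt, STAR, Picard (version 2.18.26) and RSEM, with the hg38 genome build; the versions of the others and the gene annotation are not given in the sources used here. The authors deposited a single table of log2 values for 24391 genes and 58 columns, each mapped to its sample by name. How the authors normalized before taking the log is not given in the sources used here. The values read as log2(x + 1): put back on the linear scale, library totals lie between 540370 and 1335823 with a median of 901582.5, so x is close to a CPM value after a library scale factor. Fold changes below are differences on this log2(x + 1) scale, which understates changes of low genes.

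Depth was estimated from the spacing of the lowest values, which are multiples of what 1 read is worth. A median of 74.5% of low values per library (range 72.2 to 89.2%) lay on whole steps, within 0.02 of a step. That share is too low for read counts to be recovered, so no count model was used. The estimated number of reads in genes ranged from 8.9 to 74.38 megareads, with a median of 54.8 megareads. Below the limit of 20 megareads lay 6 libraries (8.9 to 12.89 megareads; 5 Non-tumor and 1 Margin), called shallow here, and the other 52 had at least 41.05 megareads. In 4 libraries (2 Margin and 2 Non-tumor) over 2500 genes were at 0 (2938 to 9178 genes), against at most 1569 in the other 54; 2 of these 4 are also among the shallow libraries. Between libraries of a group the highest correlation was 0.984 and the highest share of identical values 10.5%, so no pair was treated as a repeat of the same library.

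Gene IDs were matched to GENCODE release 29 (GRCh38), which held 24293 of them (99.6%); the match was by ID and coordinates come from that release. XIST, TSIX and Y-linked genes (40) were left out before any analysis. Genes were kept if the linear value was at least 1 in at least 11 libraries, which left 18975 genes, of which 2330 carry clone names and no gene symbol. TGFB1 is listed under a clone name and was matched by its gene ID.

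Group differences per gene were tested with limma (version 3.58.1, R version 4.3.3) in a single fit over all 58 libraries, with a mean-dependent prior variance and the donor as a random block (consensus correlation 0.171). P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called changed at an adjusted p under 0.05. Before the data were examined, 38 lists of genes were fixed from general knowledge (hepatocyte functions, liver and immune cell types, pathways and signs of RNA quality), with 474 members, 455 of them in the table and 437 kept. A list's score is the mean log2 value of its kept members. Paired differences of scores within donors were tested by an exact two-sided sign-flip permutation test, with Benjamini-Hochberg adjustment over the 38 lists. With 11 pairs the smallest p this test can give is 0.000977, and with 19 pairs 3.81e-06. Counts of changed members are given over all genes and adjusted over the list alone. To ask whether the margin moves toward the tumor in separate donors, genes were chosen in the 11 donors with all 3 tissues by a limma fit with the donor as a fixed block, and their median Margin minus Non-tumor difference was measured in the 8 donors without a tumor library. Python (version 3.11.15) with numpy, pandas and matplotlib was used for list tests and plots.

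The genes named were set by a rule fixed before the data were examined. For each comparison it takes the 10 largest rises and 10 largest falls past the threshold among genes with a mean above the median of kept genes. It leaves out rows with no symbol, immunoglobulin and T cell receptor segments, XIST, Y-linked genes and GSTM1, GSTT1 and UGT2B17, which have common inherited deletions. From each list it takes up to 3 members past the threshold with the largest change, or, where none passed, the 2 with the smallest p. Lists are described in the results where they passed the list test, or where they hold markers of innate lymphoid, NK or T cells or cytokines acting on them. Members that were not in the table, such as IL4, IL13, IL17A, IL22 and IL25, were not analysed here. Related genes with near-identical copies (the CYP2A, HLA class II and metallothionein families) share reads, so their values are less certain.

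By the codes in the titles, tissue pieces with the same donor number come from the same donor, which is why the donor enters as a block. Deviations from the group means correlated within donors (median 0.302 for Tumor with Non-tumor, 0.324 for Tumor with Margin, 0.309 for Margin with Non-tumor) more than over all pairs of libraries (0.023, 0.016 and 0.034). The correlation was over 0.1 in 7 of 11, 10 of 11 and 15 of 19 pairs, and the lowest values were −0.192, −0.026 and −0.334. Some pairs thus show no likeness within the donor.

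The gene fit was tested on simulated data with 18975 genes. For Tumor versus Non-tumor it recovered 34.3%, 85.1% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, with 0.7% of 147 calls false; for Tumor versus Margin it recovered 28.4%, 85.1% and 100%, with 5.3% of 150 calls false. It called 0 genes for Margin versus Non-tumor, where no gene had been changed. The simulated genes varied independently of one another, no library stood apart, and the most variable genes were given no change. Other splits of the real libraries gave up to 3051 calls. The simulated shares are therefore not error rates for the real data. With 11 pairs, the sign-flip test gave an unadjusted p under 0.05 in 5.8% of 2000 simulated tests with no shift and in 99.4% with a shift of 1.5 SD.

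Alternatives chosen before the data were examined were no donor block, a fixed donor block, no filter and a 10 times higher minimum, quantile normalization, centring, 1 more unit added before the log, array weights, a fold threshold, leaving out the donor code on 2 libraries and leaving out each of the 11 donors with all 3 tissues in turn. The other 15 donors were not left out in turn for the counts of genes and lists. For lists, scores relative to all genes and members scaled to unit SD were also tried. Chosen after seeing the data were leaving out the 6 shallow libraries, leaving out the 4 libraries with many genes at 0, leaving out the 7 libraries that stand apart on the first principal component and taking the donor from the column name. The 7 lie from −122.53 downwards and the next library at −67.8, a gap of 54.73, where the next widest is 17.87. They were chosen by their expression, so a p without them is no independent test. For the margin shift, donors with a library of these kinds were left out while the genes measured stayed the same.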

Results

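Total RNA was sequenced from 58 pieces of liver tissue of patients with hepatocellular carcinoma: 11 from tumors, 22 from the tumor margin and 25 from non-tumor liver. The series' title concerns how the tumor microenvironment shapes innate lymphoid cells, lymphocytes that lack antigen receptors and include NK cells and the helper-like types 1, 2 and 3. All measurements are of whole tissue, so a value for a cell type is the level of its marker genes in bulk RNA, not a count of cells. The estimated number of reads in genes, in megareads, was 41.58 to 74.38 in Tumor (median 52.39), 8.9 to 69.13 in Margin (53.67) and 9.07 to 71.92 in Non-tumor (56.04). Gene values are differences of log2(x + 1) with their standard error from limma, adjusted by the Benjamini-Hochberg method over 18975 genes. Genes named as the largest rises or falls are taken from the genes whose mean level lies above the median of the kept genes. List values are the mean difference ± SD over donors of the mean log2 value of the list's members. On the first principal component, which holds 38.8% of the variance, 7 libraries stand apart from the rest beyond the widest gap: 4 of 22 Margin, 2 of 11 Tumor and 1 of 25 Non-tumor. Their scores for secreted hepatocyte proteins were 2.15 to 5.78, against 6.87 to 12.76 in the other 51 libraries. Coordinates are from GENCODE 29 on GRCh38, and each gene is given from its annotated start to its end.

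Tumor against Non-tumor addresses how tumor tissue differs from the liver around it. Over all 58 libraries the largest rise was that of GPC3, encoding the cell-surface proteoglycan glypican-3, a tissue marker of hepatocellular carcinoma (ENSG00000147257, chromosome X, 133535745 to 133985895). It was 8.51-fold higher in Tumor (log2 difference 3.09, SE 0.53, adjusted p = 4.616e-05; higher in 9 of 11 donors). ROBO1, a receptor for SLIT guidance proteins (chromosome 3, 78597240 to 79767815), was higher in 11 of 11 donors, by 2.38 (SE 0.26, adjusted p = 3.446e-09). Among the other large rises, the basement membrane collagen gene COL15A1 rose by 2.77 (SE 0.59), POSTN, encoding the matrix protein periostin, by 2.83 (SE 0.67), COL1A1 by 2.01 (SE 0.60), the stromal surface protein gene THY1 by 1.91 (SE 0.43), the heparan sulfatase gene SULF1 by 1.90 (SE 0.58) and the endothelial diaphragm gene PLVAP by 1.84 (SE 0.37). The remaining rises named by the rule were those of AKR1B10, an aldo-keto reductase (2.73, SE 0.83), and SPP1, encoding osteopontin (2.48, SE 0.64). The rank of GPC3 depends on the setting: AKR1B10 was above it without the 7 libraries that stand apart (3.97 against 3.54) and with the donor as a fixed block in the 11 donors with all 3 tissues (3.33 against 3.03).

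Over all 58 libraries the largest fall in Tumor was that of CYP2B6, a drug-metabolising cytochrome P450, which was 20.6-fold lower (log2 difference −4.37, SE 0.87, adjusted p = 0.000272; higher in 1 of 11 donors). The related CYP2A6, CYP1A2 and CYP2A7 differed by −4.18 (SE 0.90), −4.04 (SE 0.91) and −4.00 (SE 0.72). TAT, which starts tyrosine breakdown, PCK1, of gluconeogenesis, and the mitochondrial carrier gene SLC25A47 differed by −3.96 (SE 0.94), −3.95 (SE 0.91) and −4.18 (SE 0.73). STAB2, the scavenger receptor stabilin-2 of sinusoidal endothelium (chromosome 12, 103587273 to 103766727), was 18.3-fold lower and was higher in 0 of 11 donors (−4.19, SE 0.45, adjusted p = 3.446e-09). CRHBP and FCN3, the latter encoding the lectin ficolin-3, differed by −3.98 (SE 0.50) and −3.95 (SE 0.52). Without the 7 libraries that stand apart CYP2B6 (−3.71) came after STAB2 (−4.60), FCN3 (−4.24) and CRHBP (−4.22), and with the donor as a fixed block it was −3.56 beside −4.03 for STAB2. In all, limma called 3562 of 18975 genes changed: 1593 rose, 262 of them at least 2-fold, and 1969 fell, 794 of them at least 2-fold. Under quantile normalization 59.7% of called genes rose, against 44.7% as reported. With the donor as a fixed block in the 11 donors with all 3 tissues, 710 genes passed. In that fit 30 of the 77 named genes past the threshold kept the call. POSTN (2.14), AKR1B10 (3.33), SPP1 (2.33), COL1A1 (1.67), THY1 (1.68), SULF1 (1.54), CYP1A2 (−3.15), TAT (−3.32) and PCK1 (−3.14) did not, at the values given here from that fit. The count was 5453 without the 7 libraries that stand apart.

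Among the lists, 3 of 38 changed between Tumor and Non-tumor, and each was lower in Tumor. The markers of liver sinusoidal endothelium, the fenestrated lining of the liver's capillaries, fell by 2.80 ± 1.32 (SD, n = 11 donors; lower in 11 of 11, exact sign-flip p = 0.000977, adjusted p = 0.0371). Of its 11 members 10 fell, and 10 adjusted over the list alone. CLEC4M, a C-type lectin, differed by −4.03 (SE 0.54), beside STAB2 and CRHBP above. Metallothioneins, small metal-binding proteins, fell by 2.15 ± 1.64 (lower in 10 of 11 donors, exact adjusted p = 0.0371). Of 8 members 7 fell, and 7 adjusted over the list alone, with MT1G at −3.37 (SE 0.73), MT1E at −2.56 (SE 0.54) and MT1F at −2.32 (SE 0.50). Cytochromes P450 (−2.62 ± 2.95) and the urea cycle list (−2.06 ± 2.71) were also lower in 10 of 11 donors each, without passing. The markers of Kupffer cells, the resident macrophages of the liver, fell by 1.04 ± 0.83 (lower in 10 of 11 donors, exact adjusted p = 0.0495). Of 11 members 5 fell, and 5 adjusted over the list alone. These include the scavenger receptor gene MARCO (−3.40, SE 0.51), CD5L (−3.24, SE 0.60) and TIMD4 (−1.73, SE 0.34). The small structured RNAs, kept as a sign of RNA quality and of library type, differed in the same direction by −0.58 ± 0.78 without passing (adjusted p = 0.158). Of their 9 members 2 fell, and 3 adjusted over the list alone. The Kupffer cell call was lost under quantile normalization (−0.92, adjusted p = 0.0928; range over alternatives 0.00175 to 0.0928), with members scaled to unit SD and with 1 more unit added before the log. Without the 6 shallow libraries, which leaves 10 pairs and a smallest p of 0.00195, the differences were −2.89, −2.16 and −1.07 and each adjusted p was 0.0742, the largest over the alternatives for the first and second list. Without the 7 libraries that stand apart, which leaves 8 pairs and a smallest p of 0.00781, the differences were −3.34, −2.45 and −1.21 and 0 lists passed the sign-flip test (15 at an unadjusted p under 0.05). Leaving out 1 of the 11 donors gave 0 lists for 7 of them (6 to 10 at an unadjusted p under 0.05) and 9 lists without the donor of Tumor 5. That donor's Non-tumor library, Non-tumor 7, has 4094 genes at 0 and is the 1 Non-tumor library that stands apart.

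Markers of innate lymphoid, NK and T cells did not pass as lists between Tumor and Non-tumor, though the NK and cytotoxic list passed in 1 of 8 alternatives. The type 1, 2 and 3 lists hold genes of innate lymphoid and of T helper cells, so they do not measure innate lymphoid cells alone. Bulk RNA also does not show which liver cells express their members. The mean type 3 score was 4.69 in Tumor and 4.77 in Non-tumor, above that of T cell markers (2.79 and 2.99). The NK and cytotoxic (1.85 and 2.33) and type 2 (1.85 and 2.03) scores were low, where the log2(x + 1) scale understates changes. The NK and cytotoxic list differed by −0.42 ± 0.81 (higher in 4 of 11 donors, exact adjusted p = 0.332). Of its 13 members 3 fell (5 adjusted over the list alone): KLRD1, the CD94 receptor chain (−0.96, SE 0.31), NKG7 (−0.72, SE 0.18) and PRF1, encoding perforin (−0.70, SE 0.20). The type 1 list differed by −0.37 ± 0.79 (adjusted p = 0.338). Of its 9 members 2 fell (2 adjusted over the list alone), both chains of cytokine receptors: IL18R1 (−0.90, SE 0.26) and IL12RB2 (−0.56, SE 0.18). The type 2 list differed by −0.13 ± 0.55 (adjusted p = 0.632) with 0 of 8 members past the threshold (0 adjusted over the list alone), IL1RL1, the IL-33 receptor, at −0.74 and IL17RB at −0.58. The type 3 list differed by −0.04 ± 0.37 (adjusted p = 0.763) with 0 of 7 (0 over the list alone), RORA at −0.59 and KIT at 0.49. The median over members of its gene values was 0.005, so its sign is not settled. T cell markers differed by −0.18 ± 1.08 (adjusted p = 0.677) with 0 of 14 members past the threshold (0 adjusted over the list alone), CD4 at −0.71 and CD8A at −0.72. In the list of regulatory T cells and checkpoints (−0.003 ± 0.58, adjusted p = 0.992; median over members 0.188) 1 of 11 members fell, and 1 adjusted over the list alone. This was the checkpoint receptor gene LAG3 (−1.04, SE 0.20, adjusted p = 0.000158; higher in 0 of 11 donors). The cytokines acting on innate lymphoid cells differed by −0.10 ± 0.72 (adjusted p = 0.716; median over members 0.025). Of 11 members, IL33 (−0.95, SE 0.26) and TSLP (−0.62, SE 0.22) fell and TGFB2 (0.75, SE 0.28) rose, with the same counts adjusted over the list alone. Of the genes in this paragraph past the threshold, LAG3 (−0.98) kept its call with the donor as a fixed block in 11 donors. The others lost it at these values in that fit: KLRD1 −0.88, NKG7 −0.67, PRF1 −0.72, IL18R1 −0.92, IL12RB2 −0.56, IL33 −0.93, TSLP −0.42 and TGFB2 0.61.

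Tumor against Margin sets the tumor beside the tissue at its edge. GPC3 was again the gene with the largest rise, 5.74-fold higher in Tumor (2.52, SE 0.54, adjusted p = 0.0054; higher in 8 of 11 donors). ROBO1 was higher in 11 of 11 donors (1.49, SE 0.26) and HELLPAR, a long non-coding RNA, in 10 of 11 (1.82, SE 0.37). TXNRD1, encoding a thioredoxin reductase, rose by 1.08 (SE 0.25) and SRXN1, encoding sulfiredoxin, by 1.06. Further rises were EPPK1 (1.48), TPD52 (1.15), TMEM64 (1.09), NIPAL2 (1.07) and LPGAT1 (1.07). Among genes above the median level, the largest falls were those of the macrophage gene MARCO (−2.96, SE 0.52, adjusted p = 0.00084; 7.8-fold lower), of STAB2 (−2.86, SE 0.46), of HAMP, encoding the iron hormone hepcidin (−2.79, SE 0.58), and of the lipid transporter gene MFSD2A (−2.69, SE 0.51). CRHBP (−2.53, SE 0.51) and FCN3 (−2.50, SE 0.53; higher in 0 of 11 donors) came next, then LINC01488 (−2.32), CDHR2 (−2.17), SDS, serine dehydratase (−2.16), and FREM2 (−2.15). MARCO (−3.03) came after STAB2 (−3.65) without the 7 libraries that stand apart, and with the donor as a fixed block (−2.74) after MFSD2A (−2.89). Of 18975 genes, 417 rose, 51 of them at least 2-fold, and 234 fell, 85 of them at least 2-fold. This count moved with the setting: it was 0 with the donor as a fixed block in the 11 donors (2713 at an unadjusted p under 0.05 by limma), so that each of the 36 named genes past the threshold lost its call. Values in that fit include ROBO1 at 1.48, GPC3 at 2.07, TXNRD1 at 1.09, EPPK1 at 1.01, STAB2 at −2.75, HAMP at −2.77 and FCN3 at −2.66. The count was 267 without the block, 122 to 1295 when 1 of the 11 donors was left out, and 3792, with all 36 called, without the 7 libraries that stand apart.

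Liver sinusoidal endothelium was the list that changed between Tumor and Margin, 1 of 38. It fell by 2.09 ± 1.26 (SD, n = 11 donors; lower in 11 of 11, exact adjusted p = 0.0371), with 10 of 11 members lower (11 adjusted over the list alone) and CLEC4M at −2.78 (SE 0.55). The NK and cytotoxic list differed by −0.26 ± 0.73 (adjusted p = 0.457); 1 of 13 members fell (5 adjusted over the list alone), PRF1 at −0.83 (SE 0.21). T cell markers differed by −0.43 ± 0.96 (adjusted p = 0.441) with 0 of 14 members past the threshold (8 lower adjusted over the list alone), CD8A at −0.94 and TRBC1 at −0.67. The type 1, 2 and 3 lists differed by −0.29 (adjusted p = 0.476), −0.24 (0.441) and 0.08 (0.94), with 0 of 9, 0 of 8 and 0 of 7 members past the threshold. Adjusted over the list alone, 2, 0 and 0 members were lower; the gene values of the type 3 list had a median of −0.018. Their members with the smallest p were TBX21 (−0.59) and CCL5 (−0.83), GATA3 (−0.52) and KLRG1 (−0.46), and AHR (0.39) and LTB (−0.28). Regulatory T cell and checkpoint genes differed by −0.13 (adjusted p = 0.597), with LAG3 at −0.60 and TOX at −0.58, and the cytokines by −0.28 ± 0.52 (adjusted p = 0.441), with IL33 at −0.65 and IL10 at −0.44. In either list 0 of 11 members passed over all genes, and adjusted over the list alone 1 and 0 were lower. The sinusoidal call was lost when scores were taken relative to all genes (−2.09, adjusted p = 0.0742; range over alternatives 0.0019 to 0.132) and under quantile normalization (−2.06). It was also not reached without the shallow libraries (−2.13, 10 pairs), those with many genes at 0 (−2.21, 9 pairs) or those that stand apart (−2.38, 8 pairs). There the smallest p possible is 0.00195, 0.00391 and 0.00781, at which a single list of 38 cannot pass.

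Margin against Non-tumor asks what sets the tissue beside the tumor apart from liver farther away. The largest rise was that of SPP1 (chromosome 4, 87975650 to 87983426), 5.81-fold higher in Margin (2.54, SE 0.51, adjusted p = 0.0076; higher in 17 of 19 donors). The other leading rises were those of POSTN (2.10, SE 0.53), COL15A1 (1.96, SE 0.47), SULF1 (1.86, SE 0.46), COL1A1 (1.75, SE 0.48), THBS2 (1.62, SE 0.38), CCDC80 (1.6), the cadherin gene CDH11 (1.6, SE 0.35), COL1A2 (1.53) and FNDC1 (1.52). The falls were led by genes of cytochromes P450, alcohol dehydrogenases and a glucuronosyltransferase: CYP1A2 (−2.36, SE 0.72), ADH4 (−2.30, SE 0.69), CYP2E1 (−2.07, SE 0.71), CYP2B6 (−2.06, SE 0.69), CYP2C8 (−2.04), UGT2B10 (−2.01) and ADH1B (−2.01). The plasma protein genes TTR (−2.02) and APOC3 (−1.99) and MAT1A (−2.01), which makes S-adenosylmethionine, fell by similar amounts. Of 18975 genes, 1118 rose, 122 of them at least 2-fold, and 2070 fell, 478 of them at least 2-fold. The share that rose was 35.1%, against 51.9% under quantile normalization and 45.3% with libraries centred on their median.

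The depth of libraries differed between these groups, since 5 of the 6 shallow libraries were Non-tumor and 1 was Margin. Without them limma called 63 genes, 62 of which were also called over all libraries, with 4513 at an unadjusted p under 0.05. Among the 74 named genes past the threshold 4 kept their call: SPP1 (2.28), LTBP2 (1.33), RPPH1 (−1.02) and TERC (−0.91). RPPH1 and TERC belong to the small structured RNAs, the list kept as a sign of RNA quality and of library type. Of the named genes that lost their call, CCN2 differed by 1.10, CIITA by 0.73, CD5 by 0.66 and TRAC by 0.63, while POSTN (1.64), CYP1A2 (−1.82) and ADH4 (−1.79) differed by less than over all libraries. The 6 shallow libraries hold too few of each tissue for a comparison among themselves. In the 33 libraries of the 11 donors with all 3 tissues, with the donor as a fixed block, limma called 0 genes. Of 18975 genes tested, 870 had an unadjusted p under 0.05 in limma, no more than chance alone gives. The gene counts of the fixed-block fit thus gave no sign of a difference between Margin and Non-tumor in these 11 donors. They do not show that there is none. The 33 libraries include Margin 1 (9178 genes at 0) and Non-tumor 7 (4094 genes at 0), which both stand apart on the first principal component. The fixed-block fit was not repeated without them. Values in that fit were lower by over 1.5 times for POSTN (0.77), COL1A2 (0.87), CYP2E1 (−0.73), CYP2B6 (−0.58), CYP2C8 (−0.73), TTR (−0.66) and MAT1A (−0.73), among others, while SPP1 was at 1.91, CCN2 at 1.13 and SLC2A1 at 1.2. Without the 4 libraries with many genes at 0 the count was 5764. Without the 7 libraries that stand apart it was 2462, and 50 of the 74 named genes kept their call. SPP1 (1.67), COL1A1 (1.08), COL1A2 (0.88) and POSTN (1.3) then differed by less and kept it, while CYP1A2 (−1.72), CYP2E1 (−1.27) and ADH1B (−0.82) did not. Among others that differed by less and kept the call were CYP2B6 (−1.07), CYP2C8 (−1.14), MAT1A (−1.10), TTR (−1.19), APOC3 (−1.21), PKM (0.62) and SLC2A1 (0.68). CD5 (0.74) and TRAC (0.70) did not differ by less.

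Among the lists, 9 of 38 changed between Margin and Non-tumor in 19 donors. The TGF-beta response rose by 0.53 ± 0.46 (SD; higher in 18 of 19 donors, exact p = 1.907e-05, adjusted p = 0.000725). Of its 11 members 3 rose, and 3 adjusted over the list alone. These were LTBP2, which encodes a matrix protein of the latent TGF-beta binding family (chromosome 14, 74498170 to 74612378; 1.5, SE 0.29), CCN2, connective tissue growth factor (1.09, SE 0.30), and PMEPA1 (0.92, SE 0.25). Without the shallow libraries the list kept its call (0.42, 14 pairs, adjusted p = 0.0232; range over alternatives 0.000725 to 0.0232). Fibroblast and matrix genes rose by 1.17 ± 1.55 (higher in 17 of 19 donors, exact adjusted p = 0.0232), 11 of 14 members and 11 adjusted over the list alone. Markers of monocytes and lipid-associated macrophages rose by 0.90 ± 1.36 (15 of 19, adjusted p = 0.0262), 6 of 11 members and 6 over the list alone, with VCAN at 1.46, GPNMB at 1.29 and SPP1 as above. Genes of antigen presentation by MHC class II rose by 0.75 ± 0.95 (17 of 19, adjusted p = 0.0136), 7 of 10 members and 9 adjusted over the list alone. CIITA, their transcriptional coactivator, was higher in 18 of 19 donors (0.76, SE 0.20), the invariant chain gene CD74 in 14 (0.86) and HLA-DMA in 16 (0.71). The 7 libraries that stand apart, 4 of them Margin and 1 Non-tumor, had scores of 7.39 to 10.04 for fibroblasts and matrix (other libraries, 4.12 to 8.5), 4.18 to 7.54 for monocytes (3.11 to 5.55) and 5.5 to 8.71 for MHC class II (4.18 to 7.7). Hepatocyte lists lay in the other direction over the same 19 donors without passing, secreted proteins at −1.90 ± 3.92 (adjusted p = 0.0928) and cytochromes P450 at −2.04 ± 3.50 (adjusted p = 0.0601). Hypoxia and glycolysis genes rose by 0.42 ± 0.69 (15 of 19, adjusted p = 0.0231). Of 14 members 4 rose and 1 fell (4 and 1 adjusted over the list alone), with HK2 at 1.31, the glucose transporter gene SLC2A1 at 1.12 (SE 0.27) and PKM at 1.08.

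Sinusoidal endothelium and metallothioneins were the lists lower in Margin than in Non-tumor. The former fell by 1.09 ± 1.43 (lower in 15 of 19 donors, exact adjusted p = 0.0231), 8 of 11 members and 8 adjusted over the list alone, with FCN3 and CRHBP at −1.45 each and CLEC4G at −1.38 (SE 0.35). The latter fell by 1.19 ± 1.82 (14 of 19, adjusted p = 0.0262), 4 of 8 members (6 over the list alone), with MT1F at −1.21, MT1E at −1.19 and MT1M at −1.18. The signs of RNA quality lay in the same direction without passing: small structured RNAs at −0.75 ± 1.25 (adjusted p = 0.0593) and mitochondrially encoded transcripts at −0.99 ± 2.28 (adjusted p = 0.123). Of 9 small structured RNAs 2 fell, RPPH1 and TERC, and 8 adjusted over the list alone. Of 11 mitochondrially encoded transcripts 1 fell, and 10 adjusted over the list alone.

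T cell markers rose in Margin by 0.42 ± 0.56 (higher in 14 of 19 donors, exact adjusted p = 0.0262). Of 14 members 4 rose (7 adjusted over the list alone), among them CD5 (0.69, SE 0.21), the costimulatory receptor gene CD28 (0.64) and the T cell receptor constant gene TRAC (0.63). The cytokines acting on innate lymphoid cells rose by 0.29 ± 0.44 (16 of 19, adjusted p = 0.0444). The 2 of 11 members that rose, also 2 adjusted over the list alone, were TGFB1 (ENSG00000105329, chromosome 19, 41301587 to 41353911; 0.68, SE 0.16, higher in 16 of 19 donors) and TGFB2 (0.66, SE 0.22). Regulatory T cell and checkpoint genes differed by 0.30 ± 0.56 without passing (16 of 19, adjusted p = 0.0704). Of 11 members IL2RA (0.70) and LAYN (0.52) rose and LAG3 (−0.44) fell; adjusted over the list alone, 3 rose and 1 fell. The NK and cytotoxic list differed by −0.01 ± 0.40 (8 of 19, adjusted p = 0.922; median over members 0.038), with 0 of 13 members past the threshold (0 adjusted over the list alone), CD160 at −0.33 and KLRD1 at −0.33. The type 1 list differed by −0.01 ± 0.53 (adjusted p = 0.952); 1 of 9 members rose (0 adjusted over the list alone), the chemokine receptor gene CXCR3 (0.46). In the type 2 list (0.10 ± 0.48, adjusted p = 0.559) 2 of 8 members fell, IL17RB, a receptor chain for IL-25 (−1.02), and PTGDR2 (−0.28); adjusted over the list alone, 2 rose and 2 fell. In the type 3 list (−0.14 ± 0.65, adjusted p = 0.56) 1 of 7 members fell, RORA (−0.62), and 2 adjusted over the list alone.

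Without the 6 shallow libraries (14 pairs) the other 8 list calls between Margin and Non-tumor were lost. The differences were then 0.85 for fibroblasts and matrix, 0.67 for monocytes, −1.03 for sinusoidal endothelium and −1.06 for metallothioneins, each with an adjusted p of 0.142. They were 0.57 for MHC class II, 0.39 for T cells and 0.29 for hypoxia and glycolysis, each with an adjusted p of 0.12, and 0.21 for the cytokines (adjusted p = 0.213). Each of these was the largest adjusted p over the alternatives of its list, the smallest being 0.00266 for fibroblasts and matrix. With members scaled to unit SD, monocytes and hypoxia also lost the call (adjusted p = 0.0535 each). Without the 7 libraries that stand apart (14 pairs), monocytes differed by 0.38, MHC class II by 0.44, fibroblasts and matrix by 0.81, the TGF-beta response by 0.38 and T cells by 0.55, and each kept its call. Hypoxia and glycolysis (0.15) lost it. Genes that lost theirs were GPNMB (0.76), CD74 (0.61), HLA-DMA (0.51), HK2 (0.66), CLEC4G (−0.82), MT1E (−0.75), MT1F (−0.97), MT1M (−0.81), CD28 (0.42), CXCR3 (0.40), IL2RA (0.53), LAG3 (−0.16), PTGDR2 (−0.21) and RORA (−0.36). The type 1 list turned to 0.19 and passed (adjusted p = 0.0457; range over alternatives 0.0457 to 0.963), and the type 2 (0.27) and regulatory T cell (0.38) lists passed too. The hepatocyte lists also passed, with secreted proteins at −1.09 and cytochromes P450 at −1.16. Small structured RNAs, a sign of RNA quality, were then at −0.84 and passed.

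**Figure D1:**
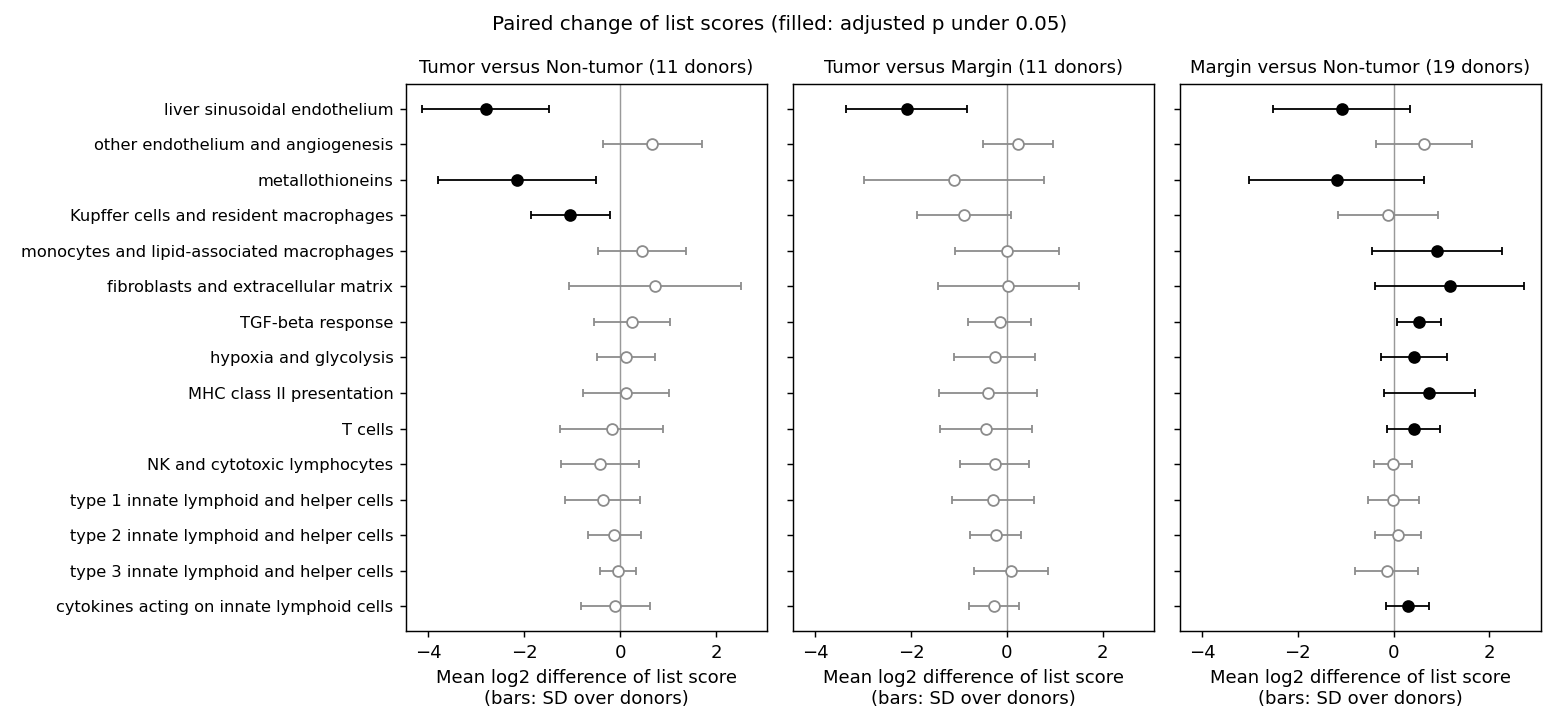
Mean paired difference of list scores (log2, x axis; bars, SD over donors) for 15 gene lists in the 3 comparisons. Filled points have an adjusted p under 0.05; sinusoidal endothelium is the list with filled points in each panel, at −2.80, −2.09 and −1.09.

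**Figure D2:**
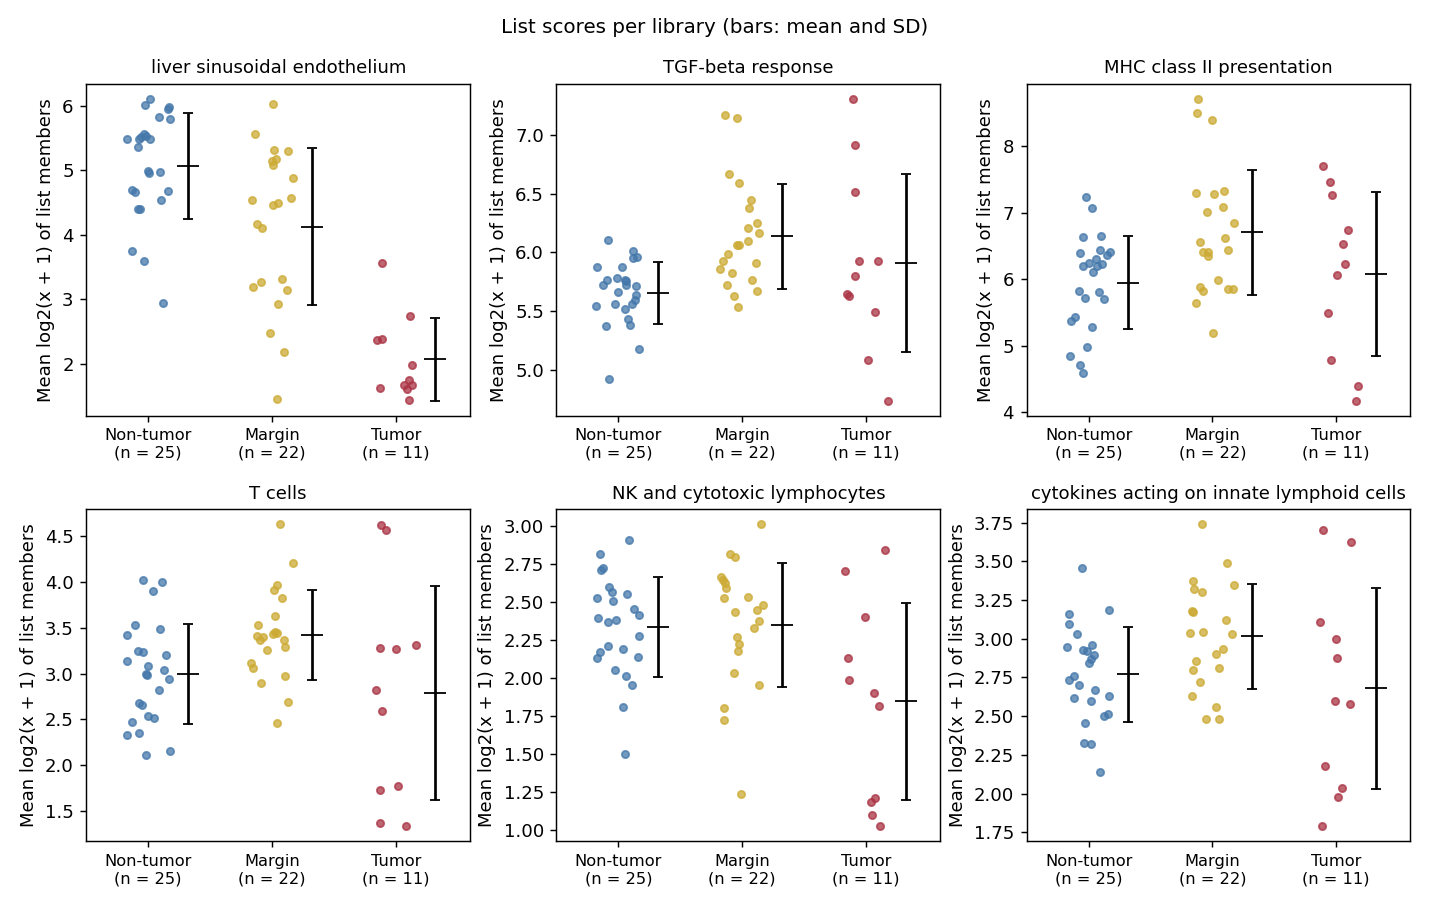
List scores per library (mean log2(x + 1) of the members, y axis) in 25 Non-tumor, 22 Margin and 11 Tumor libraries for 6 lists, with mean and SD as bars. Sinusoidal endothelium is lowest in Tumor, and the TGF-beta response of Margin lies 0.53 above Non-tumor on average over the 19 donors with both.

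Whether the margin differs from Non-tumor in the direction of the tumor was measured in donors who took no part in choosing the genes. The 243 genes that rose in Tumor versus Non-tumor in the 11 donors with all 3 tissues, by a median of 0.93, were higher in Margin in 8 of 8 donors without a tumor library. The mean of the donors' median differences was 0.44 ± 0.39 (SD, n = 8; range 0.001 to 0.98; exact sign-flip p = 0.0078, the smallest that 8 donors allow). The 467 genes that fell, by a median of 1.13 in the first donors, were lower in Margin in 8 of 8 (−0.91 ± 0.56, range −1.56 to −0.09, exact p = 0.0078). The mean over these donors of the median over all kept genes was −0.002. Of these 8 donors 3 have a shallow Non-tumor library and 3 have a Margin library that stands apart. Without the former the means were 0.47 and −0.93, and without the latter 0.18 and −0.57. Each has the same direction in 5 of 5 donors left, where the smallest p possible is 0.0625. The 3 Margin libraries that stand apart are among those with scores of 2.15 to 5.78 for secreted hepatocyte proteins. The genes measured were not separated from hepatocyte genes. A lower share of hepatocytes in the Margin pieces therefore cannot be told apart from a tumor-like change. For some lists the margin differed more in these 8 donors than in the 11. In the 11 donors, secreted hepatocyte proteins differed by −1.66 in Tumor against Non-tumor and by −1.21 against Margin, and monocytes by 0.46 and 0.001. Over all 19 donors, Margin against Non-tumor gave −1.90 and 0.90, so the 8 donors weigh heavily in those values.

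**Figure D3:**
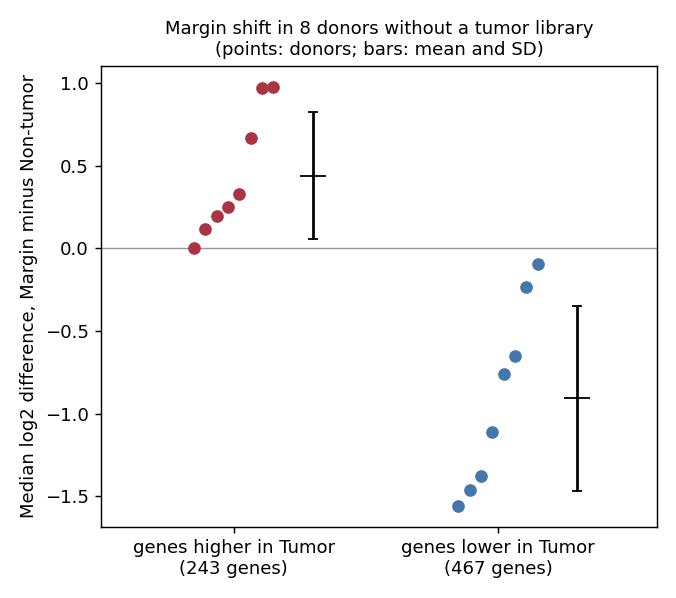
Median Margin minus Non-tumor log2 difference (y axis) in each of 8 donors without a tumor library, for 243 genes higher and 467 genes lower in Tumor in the other 11 donors; bars are mean and SD. All 8 points lie above 0 for the former and below 0 for the latter, the nearest at 0.001 and −0.09.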

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

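Leaving out the 6 shallow libraries, leaving out the 4 libraries with many genes at 0 or the 7 that stand apart on the first principal component and taking the donor from the column name were chosen after seeing the data; the other alternatives were fixed before the data were examined. The shallow libraries are 5 Non-tumor and 1 Margin, so depth is not balanced between these groups. The margin shift in the 8 donors without a tumor library kept its direction under the alternatives run. It also kept its side of the threshold, from 0.36 to 0.67 for genes that rose and from −1.39 to −0.80 for genes that fell, except where only 5 donors were left, whose smallest p is 0.0625. These were 0.47 and −0.93 without donors with a shallow library, and 0.18 and −0.57 without those with a library that stands apart. Over the 8 alternatives per list, 785 of 912 values kept direction and side of the threshold, 60 gained and 25 lost the call, and 42 changed sign. For named genes these were 3036, 138, 420 and 10 of 3604 values. Removing the filter, quantile normalization, centring, 1 more unit before the log, leaving out the donor code on 2 libraries and the donor from the column name each left the counts of changed genes within 1.5 times. Quantile normalization moved the percent of called genes that rose from 44.7 to 59.7 (Tumor versus Non-tumor) and from 35.1 to 51.9 (Margin versus Non-tumor), and centring moved the latter to 45.3; the median over all genes moved by at most 0.069. A fold threshold lowers a count by construction. The cause of the other changes below, rises among them, was not tested, except for the Margin versus Non-tumor count without the shallow libraries, by random removals.

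Counts of changed genes were 3562 (Tumor versus Non-tumor), 651 (Tumor versus Margin) and 3188 (Margin versus Non-tumor). Without the donor block they were 2802, 267 and 1368, and with the donor as a fixed block in 11 donors 710, 0 and 0. In the fixed block fit limma gave 2713 and 870 genes at an unadjusted p under 0.05 for the latter pair. Of 18975 genes tested, the 870 for Margin versus Non-tumor are no more than chance alone gives at that p. The 10 times higher minimum gave 2301, 376 and 2657, out of 11092 genes kept and not 18975, so these counts do not compare directly. Array weights gave 6965, 2978 and 7993, and a log2 fold change of at least 1 gave 1056, 136 and 600. Without the 6 shallow libraries they were 3957, 821 and 63, and without the 4 libraries with many genes at 0 they were 6244, 1203 and 5764. Without the 7 libraries that stand apart they were 5453, 3792 and 2462. Leaving out each of the 11 donors with all 3 tissues in turn gave 122 to 1295 for Tumor versus Margin, 2041 to 5572 for Margin versus Non-tumor and 2638 to 4239 for Tumor versus Non-tumor. Tumor versus Margin moved by over 1.5 times without the donor of Tumor 2 (328), 3 (1081), 4 (270), 5 (346), 6 (999), 8 (408), 9 (1295), 10 (122) and 11 (129), and Margin versus Non-tumor without that of Tumor 1 (2041) and 5 (5572). The donor of Tumor 5 has the 1 Non-tumor library that stands apart (Non-tumor 7, 4094 genes at 0). That of Tumor 1 has a shallow Margin library that stands apart (Margin 1, 9178 genes at 0).

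Counts of changed lists were 3, 1 and 9 in the same order. Relative to all genes they were 4, 0 and 14, under quantile normalization 3, 0 and 13, and without pairing, over all libraries of both groups, 15, 2 and 16. They were 0, 0 and 1 without the shallow libraries and 9, 0 and 19 without the libraries with many genes at 0. Without those that stand apart they were 0, 0 and 22 (15 and 12 lists unadjusted for the zeros), where the former pair of comparisons has 8 pairs and a smallest p of 0.00781. Leaving out 1 of these donors gave 0 to 9, 0 to 2 and 6 to 20. With 10 pairs the exact sign-flip test's smallest p is 0.00195, and 1 list alone at that p is adjusted to 0.0742, so a single list cannot pass. Without the donor of Tumor 1, 4, 6, 7, 8, 10 or 11 the first count was 0 (6 to 10 lists at an unadjusted p under 0.05), and without that of Tumor 5 it was 9 and the third 20. The second was 2 without that of Tumor 3 and 0 without any other (3 to 12 lists unadjusted). The zeros without the shallow libraries stood beside 10 and 12 lists unadjusted, and those of the second count relative to all genes, under quantile normalization and without the libraries with many genes at 0 beside 5, 7 and 12.

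Signs changed for these values, none of them past the threshold in the reported results. With a fixed block in 11 donors, MT-ND1 was −0.31 and MT-CO2 −0.34 (Tumor versus Margin) and CSF3R −0.069 (Margin versus Non-tumor). With array weights in Tumor versus Margin, F5 was −0.094, LTB 0.25, GATA2 0.020, MT-ND1 −0.51 and MT-CO2 −0.40; without the libraries with many genes at 0, MT-ND1 was −0.093 and MT-CO2 −0.078.

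Lists changed sign as follows, where the first comparison is Tumor versus Non-tumor, the second Tumor versus Margin and the last Margin versus Non-tumor. Relative to all genes, regulatory T cells were 0.064 and type 3 cells 0.030 in the first, and NK 0.057 and type 1 cells 0.060 in the last. Under quantile normalization, regulatory T cells were 0.092 and type 3 cells 0.062 in the first, and Kupffer cells 0.0039, NK 0.044 and type 1 cells 0.068 in the last. With members at unit SD, type 3 cells were 0.021 in the first, and monocytes −0.063 and fibroblasts −0.0099 in the second. With 1 more unit before the log, regulatory T cells were 0.013 in the first, mast cells 0.014 in the second and NK 0.0048 in the last. Without pairing, regulatory T cells were 0.025 in the first, monocytes −0.32, fibroblasts −0.25 and mitochondrial transcripts 0.13 in the second, and NK 0.015 and chemokines −0.016 in the last. Without the shallow libraries, mast cells were −0.099 in the first, type 3 cells −0.13 in the second, and Wnt targets 0.071, type 1 cells 0.034, type 3 cells 0.0091 and immediate early genes −0.13 in the last. Without the libraries with many genes at 0, regulatory T cells were 0.10 and cytokines 0.028 in the first, type 3 cells −0.19, fibroblasts −0.091 and small structured RNAs −0.038 in the second, and NK 0.046, type 1 cells 0.12 and type 3 cells 0.0094 in the last. Without the libraries that stand apart, type 3 cells were −0.22, fibroblasts −0.14 and small structured RNAs −0.29 in the second, and Wnt targets 0.086, type 1 cells 0.19, type 3 cells 0.070 and stellate cells 0.12 in the last.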

Other observations

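Cell cycle genes were higher in Tumor than in Non-tumor: 19 of 20 members of the proliferation list rose (20 adjusted over the list alone), with CENPF at 2.05 (SE 0.36), TOP2A at 1.98 (SE 0.35) and MKI67 at 1.78 (SE 0.34). The list score itself did not pass (1.08 ± 1.13, higher in 9 of 11 donors, exact adjusted p = 0.0649). In Tumor against Margin, 11 of the 20 rose (17 adjusted over the list alone), while the score differed by 0.79 ± 1.06 without passing (adjusted p = 0.278). In Tumor against Non-tumor, genes of general and angiogenic endothelium rose in 6 of 12 cases (8 adjusted over the list alone), with PLVAP, CD34 (1.57, SE 0.35) and ESM1 (1.17, SE 0.28) leading, while the score differed by 0.67 ± 1.03 (adjusted p = 0.241). Against Margin 0 of the 12 passed by limma (0 adjusted over the list alone). Of 11 carcinoma markers 6 rose in Tumor against Non-tumor and 2 fell (6 and 2 adjusted over the list alone); H19, an imprinted non-coding RNA, was among those that fell (−2.37, SE 0.52). In the same comparison 5 of 11 stellate cell markers fell and 2 rose (8 and 2 adjusted over the list alone), with GDF2, encoding BMP9, at −2.58 (SE 0.46) and COLEC10 at −2.47 (SE 0.60). With the donor as a fixed block in the 11 donors with all 3 tissues, CD34 (1.44), ESM1 (1.25) and COLEC10 (−2.01) lost the call in Tumor against Non-tumor. In Tumor against Margin limma then called 0 genes (2713 at an unadjusted p under 0.05), so the calls of proliferation genes there were lost too.

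Among hepatocyte functions in Tumor against Non-tumor, all 12 drug-metabolising cytochromes P450 fell (12 adjusted over the list alone), and 11 of 14 genes of the urea cycle, gluconeogenesis and amino acid breakdown (13 over the list alone). The scores differed by −2.62 ± 2.95 (adjusted p = 0.156) and −2.06 ± 2.71 (adjusted p = 0.158). Neither passed, nor did the scores of the other hepatocyte lists, in which these members fell: 7 of 14 secreted proteins (11 over the list alone), 6 of 13 genes of bile acids (9), 8 of 16 of coagulation and complement (12) and 2 of 12 of the acute phase (6), where 1 rose (1). In the 7 libraries that stand apart, 2 of them Tumor, 4 Margin and 1 Non-tumor, the scores were 0.7 to 2.2 for cytochromes (others 3.09 to 9.52) and 1.69 to 3.61 for the urea cycle list (others 5.35 to 9.81). In Margin against Non-tumor 10 of 12 cytochromes fell (12 over the list alone; score −2.04 ± 3.50, adjusted p = 0.0601), and 9 of 16 coagulation and complement genes (16 over the list alone; −1.66 ± 2.99, adjusted p = 0.0691). The chemokine gene CXCL2 was lower in Tumor (−2.12, SE 0.40) and in Margin (−1.26, SE 0.32) than in Non-tumor, and CXCL12 was lower in Tumor than in Margin (−1.55, SE 0.32). LCN2, encoding lipocalin-2, was 4.96-fold higher in Tumor than in Non-tumor (2.31, SE 0.54), while HAMP differed by −3.81 (SE 0.58). With the donor as a fixed block in the 11 donors, LCN2 (2.16), CXCL2 in Margin (−1.0) and CXCL12 (−1.39) lost the call. So did named hepatocyte genes in Tumor against Non-tumor: ALB (−2.37), APOA1 (−2.55), TF (−2.28), CPS1 (−2.68), CYP8B1 (−2.23), SLCO1B3 (−2.27), SLC27A5 (−1.87), C8A (−2.03), C9 (−1.8), F11 (−1.8) and ORM2 (−1.55), beside CYP1A2, TAT and PCK1 in the results.

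In what follows, the counts over other splits of the libraries and both tests on sinusoidal endothelium were chosen after the results were seen; the tests on shallow libraries and on chromosomes were written down before theirs, but the patterns they address had been noticed in the data. For Tumor versus Non-tumor, 1 of 100 splits of the libraries, the real one, gave as many as 3562 genes (highest other 3051). This was also 1 of 100 when tissues were swapped within donors (highest other 2535). For Margin versus Non-tumor it was 1 of 100 in both designs, against 3188 real calls and 1 as the highest other. For Tumor versus Margin 4 of 100 splits, the real one included, gave at least 651 genes, the highest other calling 1913. Swapping tissues within donors gave 2 of 100 and 815. Why some other splits gave so many calls was not tested. The share stays under 0.05 in both designs. With 100 splits, 1 of 100 is the smallest share possible, and splits of the libraries moved labels between donors. Other splits gave up to 3051 calls for Tumor versus Non-tumor and 1913 for Tumor versus Margin, so chance is not excluded there.

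The count of 3188 genes between Margin and Non-tumor fell to 63 without the 6 shallow libraries, or to 32 with the donor correlation held at its value over all libraries. Fewer libraries alone remain a possible explanation of the count, since 11 of 100 random removals of 5 Non-tumor and 1 Margin library gave as few genes (median 1738.5, lowest 0). The sizes of the differences point further: the median fold change of the 3188 genes dropped from 0.627 to 0.518 on the log2 scale, and 0 of 100 random removals went as low (lowest 0.536), so the shallow libraries may have made the differences larger. The median SE was 0.2 without them and 0.208 in the random removals. What stays open is whether depth, library kit or the donors themselves are behind this, because the shallow libraries are mostly Non-tumor and the labels do not mark the low-input kit.

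The lower sinusoidal markers in Tumor were set against 2 explanations by composition. A lower share of endothelial cells as a whole would lower other endothelial genes alike. The sinusoidal change minus theirs was −3.476 (SD 1.936, below 0 in 10 of 11 donors, exact sign-flip p = 0.00195). A changed share of hepatocytes alone would move all other cell types alike. The difference from the fibroblast and matrix genes was −3.523 (SD 2.141, 10 of 11, exact sign-flip p = 0.00195). In Margin against Non-tumor the same differences were −1.713 (SD 2.289, 17 of 19 donors, sign-flip p = 0.00425) and −2.255 (SD 2.7, 17 of 19, sign-flip p = 0.00202). The sinusoidal list thus fell relative to both lists. This does not decide on either share, because angiogenesis and matrix genes may also change their level per cell. The sinusoidal list was also taken up because of its fall, which makes a low p likely. A candidate explanation is a shift from sinusoidal to other, capillary-like endothelium, but loss of sinusoidal cells with growth of other vessels would give the same values in bulk tissue, and neither was tested.

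Among the 416 genes with a position on the numbered chromosomes or X that rose in Tumor versus Margin, 96 lie on chromosome 8 between 50000001 and 145066685 (23.5% of 408 genes there, against 2.2% of all genes), and 112 on chromosome 1 between 150000001 and 248919946 (14.5% of 775). Relative to genes of like mean level, the median gene of the regions was higher in Tumor than in Margin by 0.372 (SD 0.493, higher in 9 of 11 donors, exact p = 0.0117) and 0.206 (SD 0.283, 8 of 11, exact p = 0.0195), and than in Non-tumor by 0.418 and 0.244 (exact p = 0.00781 and 0.00195). The Margin minus Non-tumor differences in the 8 donors without a tumor library were −0.086 (SE 0.02, higher in 1 of 8) and 0.004 (SE 0.013, higher in 3 of 8). These values argue only against composition that also raises the regions in Margin over Non-tumor. Composition found in tumor tissue alone cannot be seen in these pieces, so it stays open. Gains of these chromosome arms in the tumors may underlie the rises, but copy number was not measured, and the regions were chosen because named genes that rose, such as TPD52, NIPAL2 and LPGAT1, lay there. A scan of 129 windows of 25000000 bases with at least 30 genes found 0 windows past the adjustment for Tumor versus Margin by the exact sign-flip test (24 at an unadjusted p under 0.05). With 11 pairs the smallest p of this test is 0.000977, so a single window of 129 cannot pass. A rise in 9 or 8 of 11 donors, as in the 2 regions, cannot reach that p, so the 0 does not decide on them. For Tumor versus Non-tumor 4 lower windows passed: 2 on chromosome 1 from 50000001 to 100000000, 1 on 4 from 175000001 and 1 on 9 from 25000001. They differed by −0.146 to −0.291 and were lower in 11 of 11 donors (exact sign-flip test, adjusted p = 0.0315 each).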
